A study of Mus musculus with 12 samples.

How the data were processed

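The tissue was mouse cerebral cortex at embryonic day 16.5, hybridised to Affymetrix oligonucleotide arrays (U74Av2 by the platform annotation). There were 12 arrays in 6 groups of 2: medial, dorsal, ventral, rostral and occipital pieces of the hemisphere, and the whole hemisphere. By the protocol text, poly(A)+ RNA was purified on oligo dT columns and copied into biotin-labelled cRNA. The labels give the molecule as total RNA, and the protocol text was followed here. By the labels, the cRNA was hybridised to arrays that were each scanned 2 times, and replicates came from independent dissections. The titles name a rostral piece where the protocol text lists a lateral piece, and the titles were followed here.

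The deposited value per probe set is Affymetrix's average difference, the mean of perfect-match minus mismatch probe signals. It is linear and can be negative. The labels' account of the data analysis breaks off after naming this quantity, so the software version is unknown. As deposited, these intensities had been scaled per array by the authors to a common trimmed mean: the 2% trimmed means of the 12 arrays lay between 2501.6 and 2501.9, a spread of 0.0118%. No further scaling was applied.

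Values under a floor of 693.5, the root mean square of all negative values, were set to that floor before taking log2. Of 12488 probe sets, 66 are controls and were left out. Those above 1387, which is 2 times the floor, on at least 2 of the 12 arrays were tested, which gave 5832 probe sets (46.9%). The platform annotation pairs 5292 of the tested probe sets with exactly 1 gene symbol, which makes 4562 genes, 212 with several symbols and 328 with none. A table of RefSeq genes (assembly GRCm38.p6), matched by gene ID, changed 0 of the symbols.

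Differences were tested in R 4.3.3 with limma 3.58.1, in 1 fit with a mean for each of the 6 groups, 6 residual degrees of freedom and 2.86 prior degrees of freedom. All p-values are two-sided and adjusted by Benjamini and Hochberg over the 5832 probe sets within each comparison, with a threshold of 0.05. A region was set against the unweighted mean of the other 4 regions, so n = 8 beside such a mean counts the arrays of those 4 regions. A log2 difference is followed by its standard error (SE), and a mean average difference by its standard deviation (SD). Folds come from the floored log2 means, and a fold is given as "at least" where every array of the lower side is at the floor. Equal replicate numbers were not treated as a block, because the labels do not say that they share a dissection.

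Gene lists were compared with all other tested genes by camera in limma, with a preset correlation of 0.01 between genes and 1 probe set per gene, the one with the highest mean. Of 26 lists, 21 had at least 5 tested members, which made 105 tests over 5 regions, adjusted together. Of these, 33 passed, 16 upward and 17 downward. With an estimated correlation 0 of the 105 camera tests in limma passed, and the smallest adjusted p was 0.242; that value stands beside each list.

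The comparisons, the floor, the filter, the lists and the rule for naming genes were fixed before the data were examined. The rule took genes past the threshold whose difference had the same sign in replicate 1 and replicate 2. It named the 10 largest differences in each direction for a region, 5 for rostral against occipital and for dorsal against ventral, 2 for a region against the hemisphere, and the 10 largest F for the test over all regions. Where 0 genes passed, it named the 5 with the smallest p. Members of the lists were named in addition. Where a gene has several probe sets, the named gene's values are those of the probe set with the highest mean over the 12 arrays among the probe sets that passed.

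In simulated data with the spread of these arrays, 100 probe sets changed by 1 log2 unit and 100 changed by 2 among 5832. For ventral against the other 4 regions, 56% of the smaller and 88% of the larger changes were recovered, with 14 false calls among 158. For rostral against occipital, with 2 arrays on each side, the shares were 44% and 78%, with 11 false calls among 133. The simulated arrays varied independently, with 1 spread per probe set for all groups. The deposited rostral and occipital arrays differed in opposite directions in the replicates. These shares therefore do not tell what that comparison could have found.

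The alternatives tried were other floors, no filter and a stricter filter, quantile normalization, an arcsinh scale, limma with a trend and robust variances, replicate number as a block, a fit of only the arrays compared, camera with an estimated correlation or with means over probe sets, and each array left out in turn. A reference mean without the ventral piece and a fit without the arrays labelled rostral or occipital were added after the data were seen.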

Results

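The data are mRNA levels in 5 pieces of the embryonic mouse cerebral hemisphere and in the whole hemisphere, with 2 arrays per group from independent dissections. The series asks how gene expression differs between parts of the developing cortex. Between 39.1% and 41.7% of the probe sets of an array lay above 2 times the floor, and between 16.9% and 21.7% were negative. Array medians ran from 737 to 851. Replicates of a group correlated at r = 0.901 to 0.962 across probe sets and arrays of different groups at 0.854 to 0.969. For 10 of the 12 arrays the closest array of another group had the same replicate number. The exceptions were rostral replicate 2 and occipital replicate 1, each the closest of the other (r = 0.963). Hemisphere replicate 2 correlated at 0.969 with occipital replicate 2 and at 0.901 with its own replicate. The main fit has no block, so what arrays of a number share stays in its spread. Probe sets are not independent replicates. The ratio of the 5' to the 3' probe set of beta-actin, a measure of cDNA length, was 0.604 to 0.831 on the arrays numbered 1 and 0.804 to 0.887 on those numbered 2. The same ratio of GAPDH was 0.982 to 1.16 and 0.979 to 1.14. The small number of arrays limits the precision of every value.

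Over the 5 regions together, the ventral and the medial piece held most of the extremes. The neuropeptide gene Npy was highest in the dorsal piece and lowest in the medial piece, with a 5.92-fold span (adjusted p = 0.000943 for this gene and for Scg2). Scg2, which encodes the secretory granule protein secretogranin II, and Vsnl1, a neuronal calcium sensor, were highest in the ventral and lowest in the medial piece, with spans of at least 12.6-fold and of 10.3-fold. The growth factor midkine (Mdk, 8.36-fold), the mitotic kinase Cdk1 (5.98-fold), the growth arrest gene Gas1 (5.49-fold) and Eomes, a transcription factor of intermediate progenitors (at least 12.1-fold), had their highest mean in the medial and their lowest in the ventral piece. The other genes among the 10 largest F were the chemokine gene Ccl4, highest in the dorsal piece, and Resp18 (at least 4.82-fold) and Ripor2 (5.30-fold), both highest in the ventral piece. limma's F-test passed 190 probe sets, or 170 genes. The highest mean was ventral for 85 of these probe sets, medial for 82, dorsal for 17, rostral for 4 and occipital for 2. The lowest was ventral for 95, medial for 73, dorsal for 20, rostral for 1 and occipital for 1. For many probe sets the rostral minus occipital difference reversed between the replicates, as described below. Where it did, the rostral and the occipital mean each average unlike values. Their low counts therefore do not show that these pieces lack differences of their own. The count was 442 with replicate number as a block and 383 without the arrays labelled rostral or occipital. It was 13 and 11 without ventral replicate 1 and 2, 73 and 67 without medial replicate 1 and 2, and 75 without either dorsal replicate.

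**Figure D1:**
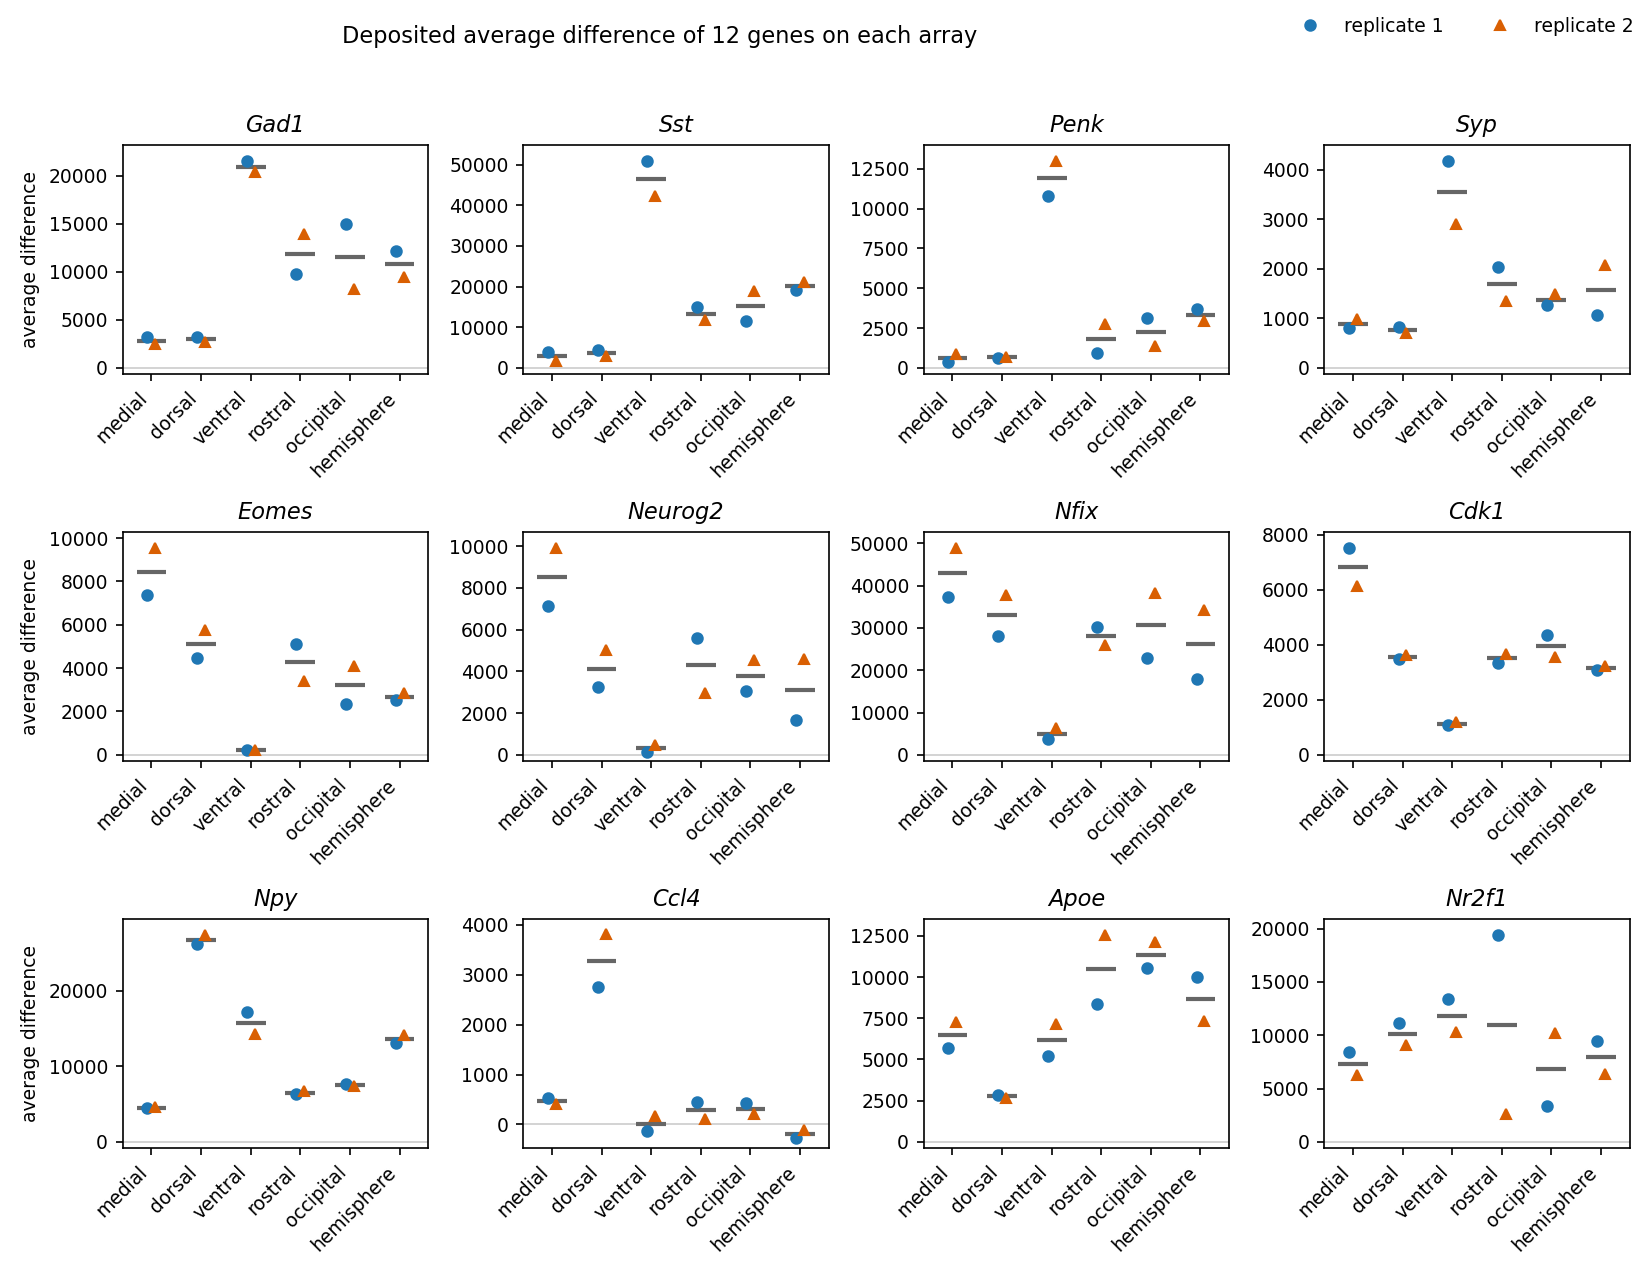
Average difference (vertical axis, linear scale) of 12 genes in the 5 regions and the whole hemisphere; circles are replicate 1, triangles are replicate 2 and bars are the mean of the 2 arrays. Sst and Penk are highest on both ventral arrays, Npy and Ccl4 on both dorsal arrays, and Nr2f1 is 19403 and 2614 on the arrays labelled rostral.

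The ventral piece was compared with the other 4 regions to find what sets the base of the hemisphere apart. Of the genes of GABAergic cells 6 of 15 rose and 1 fell there, and of those of synaptic transmission 9 of 20 rose. Of the cell cycle genes 19 of 30 fell, and of those of pallial projection neurons 6 of 14 fell and 1 rose. With an estimated correlation the camera adjusted p of these 4 lists was 0.242, 0.368, 0.242 and 0.455. Somatostatin (Sst), a neuropeptide of inhibitory interneurons, reached an average difference of 46545 ± 6168 (SD, n = 2) in the ventral piece against 8754 ± 6371 (SD, n = 8), a 7.11-fold rise (log2 2.83 ± 0.31 SE, adjusted p = 0.00155). Eomes was 236 ± 6.15 (SD, n = 2) against 5261 ± 2297 (SD, n = 8), at least 6.98-fold lower (log2 -2.80 ± 0.24 SE, adjusted p = 0.000624). Its other probe set differed by -1.23 in log2. limma passed 571 probe sets, 248 higher and 323 lower, or 209 and 285 genes, and all 571 had the same sign in both replicates. With 2 arrays per region, passing nearly requires the same sign in both. Such agreement among passing probe sets is no separate support, here or in the comparisons below.

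The largest rise in the ventral piece was that of proenkephalin (Penk), a precursor of opioid peptides, which rose 10.3-fold (adjusted p = 0.00195), from 1339 ± 1032 (SD, n = 8) to 11894 ± 1542 (SD, n = 2), on a probe set of the kind that can match several members of a sequence family. Its other probe set differed by 0.81 in log2. Ngef rose 7.29-fold, and Fxyd7, a regulator of the sodium pump, 6.83-fold. The homeobox gene Pbx3 rose 6.54-fold (adjusted p = 0.00411). The rises of Scg2 (5.46-fold), Vsnl1 (4.97-fold), the neuronal surface glycoprotein Thy1 (4.76-fold), the calmodulin-binding protein neurogranin (Nrgn, 4.51-fold, adjusted p = 0.0383) and Rasgrp2 (4.48-fold), an exchange factor for Rap GTPases, complete the 10 largest. For Fxyd7, Nrgn and Rasgrp2, 6 of the 8 other arrays were at the floor, so their folds depend on it. Fxyd7 averaged 5524 ± 649 (SD, n = 2) against 195 ± 942 (SD, n = 8).

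The largest fall in the ventral piece was that of Insm1, a zinc finger factor of neuronal progenitors, which fell 7.66-fold from 9404 ± 2358 (SD, n = 8) to 1302 ± 729.9 (SD, n = 2; adjusted p = 0.00159). Neurog2, the proneural factor of the dorsal telencephalon, was at least 6.86-fold lower (adjusted p = 0.00351). The nuclear factor I genes Nfix (6.72-fold) and Nfib (5.85-fold, adjusted p = 0.0157) fell, as did Mdk (6.50-fold, log2 -2.70 ± 0.17 SE, adjusted p = 0.00025), the semaphorin receptor Nrp1 (5.60-fold) and Fezf2, which specifies subcerebral projection neurons (5.51-fold, adjusted p = 0.00277). Lima1, an actin-binding protein, was at least 4.94-fold lower, and Ckap2, a mitotic spindle protein, at least 4.08-fold lower.

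Among 15 tested genes of the ganglionic eminences and GABAergic cells, 6 rose and 1 fell in the ventral piece (9 and 1 adjusted over the list alone). The vesicular GABA transporter Slc32a1 averaged 12079 there against 3752, the GABA-synthesising enzyme Gad1 20952 against 7309, and Calb1, Npy and the interneuron factor Lhx6 also rose, by 1.95, 0.84 and 0.69 in log2. The chemokine receptor gene Cxcr4, used by migrating interneurons, fell (-1.13), and Dlx1 (0.33) and Dlx2 (0.06) did not pass. The list's median difference was 0.84 (camera adjusted p = 4.46e-06, and adjusted p = 0.242 with an estimated correlation). Of 20 synaptic transmission genes 9 rose and 0 fell by limma (10 and 0 adjusted over the list alone), among them the vesicle proteins Syp (1.65) and Syn2 (1.67), the kainate receptor subunit Grik1 (1.27) and the fusion protein Stx1a (1.13). The median was 0.59 (adjusted p = 3.1e-06, and adjusted p = 0.368 with an estimated correlation). In the list of neuronal cytoskeleton and identity, 4 of 24 rose and 0 fell by limma (4 and 0 adjusted over the list alone): Nefl (by 2.83-fold), and in log2 Eno2 (1.07), Gap43 (0.82) and Stmn4 (0.61). Its median was 0.30 (adjusted p = 0.000217, and adjusted p = 0.285 with an estimated correlation). Of 10 striatal projection neuron genes, 4 rose and 0 fell by limma (4 and 1 adjusted over the list alone), namely Penk, Pbx3, the tachykinin precursor Tac1 (3656 against 730) and the dopamine receptor Drd2 (1668 against 742). Foxp1 (0.41), Meis2 (0.66) and Pde1b (-0.64) did not pass, and the list's median was 0.66 (adjusted p = 0.0429, and adjusted p = 0.455 with an estimated correlation). The striatal list lost its call without ventral replicate 1 (adjusted p = 0.0911), without medial replicate 1 (0.0548) or 2 (0.0520), without either hemisphere array (0.0940) and with replicate number as a block (0.152). Of 9 genes of the ventrolateral pallium, piriform cortex and amygdala, 2 rose (Npy and the growth factor Tgfa, 1.45) and 0 fell by limma (3 and 0 adjusted over the list alone), with a median of 0.80 (adjusted p = 0.00609, and adjusted p = 0.369 with an estimated correlation), a call lost without the filter (0.0836).

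Cell cycle genes were lower in the ventral piece. Of 30 tested, 0 rose and 19 fell by limma (0 and 23 adjusted over the list alone), including Cdk1 (-1.91), the ribonucleotide reductase subunit Rrm1 (-1.84), the replication licensing factor Mcm2 (-1.53), the mitotic checkpoint target Cdc20 (-1.48) and the proliferation marker Mki67 (-1.37). The list's median was -1.14 (camera adjusted p = 1.1e-15, and adjusted p = 0.242 with an estimated correlation). Of 21 radial glia genes 0 rose and 5 fell by limma (0 and 11 adjusted over the list alone): Sox3 (-1.77), the apical membrane protein prominin 1 (Prom1, -1.45), Tead2 (-1.35), Aldoc (-1.24) and Dbi (-0.80). Sox2 (-0.10) and Fabp7 (0.13) did not pass. The median was -0.65 (adjusted p = 4.93e-05, and adjusted p = 0.242 with an estimated correlation). Among 14 genes of pallial projection neurons 6 fell (Eomes, Neurog2, Nfix, Nfib, Fezf2 and Neurod6, the last by -1.26) and Nrgn rose (8 and 2 adjusted over the list alone), while the deep-layer factor Tbr1 (0.20, adjusted p = 0.58) did not pass. The median was -0.99 (adjusted p = 0.002, and adjusted p = 0.455 with an estimated correlation). Of 19 Wnt pathway genes the receptors Fzd8 (-1.04) and Fzd2 (-1.17) and the secreted antagonist Sfrp1 (-1.86) fell and the transcription factor Tcf7l2 (1.35) rose (6 down and 1 up adjusted over the list alone). The Tcf7l2 probe set is of the kind that can match several members of a sequence family. The list's median was -0.32 (adjusted p = 0.0382, and adjusted p = 0.577 with an estimated correlation), and this call was lost without ventral replicate 1 (0.227), medial replicate 2 (0.0519) or dorsal replicate 2 (0.0541), and without the filter (0.16).

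The 2 ventral arrays carried much of the count of 571, which was 91 without ventral replicate 1 and 155 without ventral replicate 2, and it was 569 without the arrays labelled rostral or occipital and 938 with replicate number as a block. Of 85 genes named for this comparison, 61 lost their call without ventral replicate 1 and 43 without replicate 2, while 23, among them Sst, Penk, Scg2, Slc32a1, Eomes, Insm1, Nfix, Mdk, Cdk1 and Mcm2, kept it whichever single array was left out. The beta-actin ratio of ventral replicate 1 was 0.665, below the 0.706 to 0.831 of the other regions' arrays of that number, and that of ventral replicate 2 was 0.856, within 0.840 to 0.887. The GAPDH ratio of ventral replicate 1 was 0.982, below the 1.05 to 1.16 of the other regions. That of ventral replicate 2 was 1.09, within 1.00 to 1.14.

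**Figure D2:**
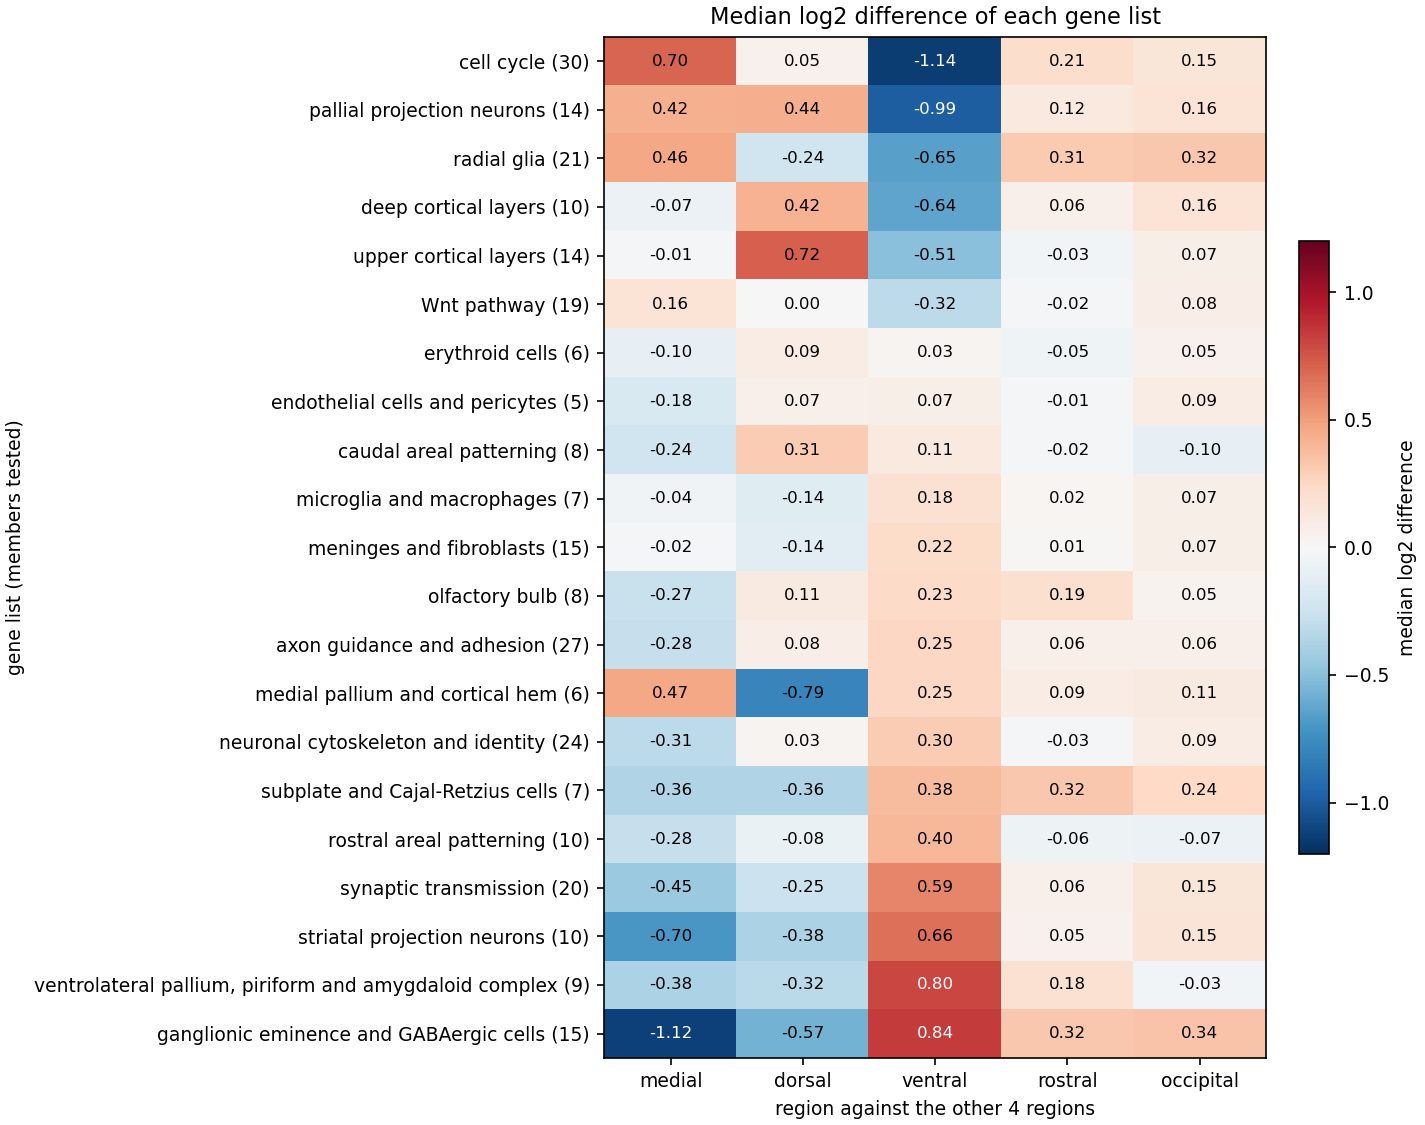
Median log2 difference of the tested members of 21 gene lists (vertical axis, members tested in brackets) in each region against the other 4 regions (horizontal axis); the colour scale runs from blue (lower) to red (higher). The cell cycle list has a median of -1.14 in the ventral and 0.70 in the medial piece, and the GABAergic list 0.84 and -1.12.

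Dorsal against ventral asks what distinguishes the ends of the dorso-ventral axis. Penk was at least 17.1-fold lower in the dorsal piece (657 ± 44.2 against 11894 ± 1542, SD, n = 2 each; adjusted p = 0.00404), on the probe set that can match a sequence family, while its other probe set differed by -0.90 in log2. Sst was 13.2-fold lower there (3586 ± 1004 against 46545 ± 6168, SD, n = 2 each; adjusted p = 0.00246). Pbx3 (10.9-fold), Ngef (9.98-fold) and Fxyd7 (at least 7.94-fold) were also lower in the dorsal piece. On the dorsal side Insm1 was 9.04-fold higher (adjusted p = 0.00496), Eomes at least 7.31-fold (adjusted p = 0.00246, with 1.09 in log2 for its other probe set), Nfix 6.68-fold, Neurog2 at least 5.81-fold and Mdk 5.75-fold. limma passed 308 probe sets, 145 higher in the dorsal and 163 higher in the ventral piece, or 127 and 142 genes, each with the same sign in both replicates. The differences of the replicates correlated at r = 0.77 across probe sets. The count was 587 with replicate number as a block, 54 and 49 without dorsal replicate 1 and 2, and 55 and 85 without ventral replicate 1 and 2. Penk, Sst, Eomes and Mdk kept their calls in each of these.

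The medial piece, which borders the midline, was compared with the other 4 regions to find what sets it apart. Of the cell cycle genes 6 of 30 rose there, and of the GABAergic genes 4 of 15 fell (camera adjusted p = 0.242 for either list with an estimated correlation). Eomes rose 3.23-fold, to 8452 ± 1542 (SD, n = 2) from 3207 ± 2103 (SD, n = 8; log2 1.69 ± 0.24 SE, adjusted p = 0.0194), and its other probe set differed by 1.09. Scg2 was at least 4.35-fold lower, with 274 ± 173 (SD, n = 2) against 3826 ± 3089.9 (SD, n = 8; log2 -2.12 ± 0.16 SE, adjusted p = 0.00172). limma passed 74 probe sets, 30 higher and 44 lower, or 30 and 35 genes, all 74 with the same sign in both replicates.

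Among the largest rises in the medial piece were Cdk1 (2.48-fold, 6813 ± 986, n = 2, against 3035 ± 1209, n = 8, SD; adjusted p = 0.00694), the homeodomain-only protein gene Hopx (2.39-fold, adjusted p = 0.0187), Mdk (2.19-fold, adjusted p = 0.0211) and Igfbp3, a binding protein of insulin-like growth factors (2.75-fold, adjusted p = 0.0499). The immediate early gene Ier2 (2.19-fold), the stress response gene Gadd45g (2.12-fold), the membrane linker ezrin (Ezr, 2.10-fold), Pter (2.23-fold, adjusted p = 0.00673) and the mitochondrial enzyme Tst (2.10-fold) rose too. For Pter 6 of the 8 other arrays were at the floor, so its fold depends on it. The largest falls included Pbx3 (7.18-fold, adjusted p = 0.0187), Sst (5.10-fold, 2849 ± 1583, n = 2, against 19678 ± 17532, n = 8, SD), Gad1 (3.37-fold, adjusted p = 0.0187), Slc32a1 (3.17-fold) and Npy (2.65-fold, 4516 ± 51.0, n = 2, against 14120 ± 8734, n = 8, SD; adjusted p = 0.0033). The membrane fusion genes Nsf (2.89-fold) and Stx1a (2.87-fold, adjusted p = 0.00694), Vsnl1 (3.70-fold) and the huntingtin-associated protein gene Hap1 (2.53-fold) fell as well.

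Of the 30 cell cycle genes 6 rose and 0 fell in the medial piece by limma (19 and 0 adjusted over the list alone): Cdk1, Mcm2, Cdc20, Ccnb2, Rrm1 and Hmgb2. The median was 0.70 (camera adjusted p = 1.1e-15, and adjusted p = 0.242 with an estimated correlation). Radial glia genes had a median of 0.46 (adjusted p = 0.000507, and adjusted p = 0.285 with an estimated correlation). Of the 21, Hopx passed (8 up and 1 down adjusted over the list alone), and the progenitor factor Pax6 at 0.87 (adjusted p = 0.059) did not pass. In the GABAergic list 4 of 15 fell, Npy, Sst, Gad1 and Slc32a1, and 0 rose by limma (9 and 0 adjusted over the list alone), with a median of -1.12 (adjusted p = 7.04e-09, and adjusted p = 0.242 with an estimated correlation). Stx1a, Syt1 (-1.23) and Syt5 (-0.88) were the 3 of 20 synaptic genes that fell (8 adjusted over the list alone; median -0.45, adjusted p = 1.48e-06, and adjusted p = 0.338 with an estimated correlation). The neuronal cytoskeleton list had a median of -0.31 with 0 of 24 members passing in limma (1 down adjusted over the list alone; adjusted p = 2.61e-06, and adjusted p = 0.242 with an estimated correlation). Among 27 genes of axon guidance and adhesion, the ephrin receptor Epha7 (-0.93), the ligand Efnb3 (-0.93) and the netrin receptor Unc5c (-1.01) fell (5 adjusted over the list alone; median -0.28, adjusted p = 0.00192, and adjusted p = 0.537 with an estimated correlation). That call was lost without medial replicate 1 (0.2). The ventrolateral pallium list (median -0.38, adjusted p = 0.000945, and adjusted p = 0.287 with an estimated correlation) had Npy as its passing member (2 down adjusted over the list alone), and lost its call without the filter (0.0673). The striatal list (median -0.70, adjusted p = 0.0212, and adjusted p = 0.435 with an estimated correlation) had Pbx3 (3 down adjusted over the list alone), and this call was lost without medial replicate 1 (0.0548), without either hemisphere array (0.0580) or with replicate number as a block (0.108). The 6 tested genes of the medial pallium and cortical hem had a median of 0.47 with 0 passing in limma, over all probe sets or adjusted over the list alone (camera adjusted p = 0.195).

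The medial arrays had the highest GAPDH ratio of their number, 1.16 and 1.14. Transthyretin (Ttr), an abundant transcript of the choroid plexus, did not pass in the medial piece (1.52, adjusted p = 0.134). It measured 2151 and 4564 on the medial, 1228 and 3527 on the occipital, 2058 and 971 on the rostral, 329 and 84.2 on the ventral and 74.5 and 49.8 on the dorsal arrays. With ventral left out of the reference 5 probe sets passed, Npy (-1.27), Scg2 (-1.61), Stx1a (-1.32) and Vsnl1 (-1.40) lower and Pter (1.14) higher, and the cell cycle and GABAergic medians were 0.48 and -0.92. The count of 74 was 256 with replicate number as a block and 166 without the arrays labelled rostral or occipital, with 95 higher and 71 lower, so that most were higher. It was 10 and 0 without medial replicate 1 and 2 (limma, with 559 at an unadjusted p under 0.05 and all 30 named genes lost without the latter). It was 23 and 6 without dorsal replicate 1 and 2, 8 and 9 without ventral replicate 1 and 2, 46 without rostral replicate 2, 40 without occipital replicate 2 and 124 without either hemisphere array.

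The dorsal piece was compared with the other 4 regions in the same way. It had the highest levels of Npy and of the chemokine gene Ccl4, and lower levels of the GABA-synthesising enzyme Gad1 and of apolipoprotein E (Apoe). Npy was 26749 ± 878 (SD, n = 2) against 8562 ± 4654 (SD, n = 8), a 3.49-fold rise (log2 1.80 ± 0.12 SE, adjusted p = 0.000394). Ccl4 was 3284 ± 761 (SD, n = 2) against 272 ± 225 (SD, n = 8), with all 8 other arrays at the floor, so at least 4.67-fold higher (adjusted p = 0.000394). limma passed 16 probe sets, 7 higher and 9 lower, or 6 and 8 genes, all 16 with the same sign in both replicates.

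The other rises in the dorsal piece were Nfe2l3, a bZIP transcription factor (at least 2.63-fold, adjusted p = 0.0147), the TGF-beta receptor Tgfbr1 (2.14-fold, adjusted p = 0.0147), the actin-binding protein Ablim1 (1.86-fold, adjusted p = 0.0494) and the sodium-calcium exchanger Slc8a1 (1.84-fold, adjusted p = 0.0469). Falls were seen for Pbx3 (4.67-fold, log2 -2.22, adjusted p = 0.0469, with -2.07 and -1.60 for its other probe sets), the sialyltransferase St6galnac5 (4.27-fold, 676 ± 62.3, n = 2, against 3147 ± 948, n = 8, SD; adjusted p = 0.00562), the calcium-binding protein calretinin (Calb2, 3.76-fold, adjusted p = 0.0391), Ripor2 (3.23-fold), Gad1 (3.16-fold, adjusted p = 0.0396), Apoe (2.98-fold, adjusted p = 0.0295), Tmeff2 (at least 2.33-fold) and Resp18 (at least 2.05-fold).

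In the GABAergic list Npy rose and Gad1 fell in the dorsal piece (1 up and 6 down adjusted over the list alone), with a median of -0.57 (camera adjusted p = 2.95e-06, and adjusted p = 0.242 with an estimated correlation). Synaptic genes had a median of -0.25 and 0 of 20 passed in limma (4 down adjusted over the list alone; adjusted p = 2.81e-05, and adjusted p = 0.382 with an estimated correlation). The medial pallium and cortical hem genes had a median of -0.79 and 0 of 6 passed in limma (3 down adjusted over the list alone; adjusted p = 0.000845, and adjusted p = 0.242 with an estimated correlation). Among 7 subplate and Cajal-Retzius genes Calb2 fell (1 up and 3 down adjusted over the list alone; median -0.36, adjusted p = 0.00301, and adjusted p = 0.242 with an estimated correlation). Upper layer genes had a median of 0.72 and 0 of 14 passed in limma (1 up adjusted over the list alone, Cux1 at 0.92; adjusted p = 0.0163, and adjusted p = 0.338 with an estimated correlation). Their call was lost without dorsal replicate 2 (0.329), ventral replicate 1 (0.0538) or the ventral piece in the reference (0.0596). The pallial projection list had a median of 0.44 and 0 of 14 passed in limma (0 adjusted over the list alone; adjusted p = 0.0124, and adjusted p = 0.577 with an estimated correlation), and its call was lost without dorsal replicate 2 (0.437), ventral replicate 1 (0.0517) or the ventral piece in the reference (0.551). Radial glia genes had a median of -0.24 and 0 of 21 passed in limma (1 down adjusted over the list alone; adjusted p = 0.000845, and adjusted p = 0.287 with an estimated correlation), a call lost without dorsal replicate 1 (0.0563) or without the arrays labelled rostral or occipital (0.161).

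With ventral left out of the reference 8 probe sets passed for the dorsal piece: Npy (2.15), Ccl4 (2.22), Nfe2l3 (1.40), Tgfbr1 (1.07) and Ablim1 (1.04) higher, and St6galnac5 (-2.05), Apoe (-1.72) and Ripor2 (-1.45) lower. The count of 16 was 45 with replicate number as a block and 28 without the arrays labelled rostral or occipital, with 6 higher and 22 lower in the latter. The 7 higher and 9 lower were 3 and 13 with a stricter filter and 3 and 11 with a trend and robust variances. It was 2 without either dorsal replicate, 5 and 8 without medial replicate 1 and 2, 4 and 8 without ventral replicate 1 and 2, 9 without occipital replicate 1 and 7 without either hemisphere array. Of 14 named genes, Npy and Ccl4 passed in every one of these.

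By the titles, rostral against occipital asks about the rostro-caudal axis of the cortex. The protocol text lists a lateral piece in place of the rostral one, so that axis rests on the titles. The 5 genes below differed strongly between these arrays, but in opposite directions in the replicates. The caudally graded receptor gene Nr2f1 measured 19403 on rostral replicate 1 and 2614 on rostral replicate 2, and 3359 and 10243 on the occipital replicates. Its relative Nr2f2 measured 6382 and 802 on the rostral and 861 and 3442 on the occipital arrays. The zinc finger gene Zic1 (3284 and 22097 rostral, 20733 and 2878 occipital) and the basal forebrain factor Lhx8 (152 and 4648 rostral, 4665 and 617 occipital) showed the reverse order. Crym, which encodes a thyroid hormone-binding protein, measured 4974 and 295 rostral and 67 and 4191 occipital. These 5 genes were chosen after their values were seen.

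limma passed 0 of 5832 probe sets for rostral against occipital, and 62 had an unadjusted p under 0.05, where 292 are expected by chance. Taking replicate number as a block, limma gave 156 such probe sets, still with 0 passing. The 5 with the smallest p, none of which passed (adjusted p = 1 each), were Lrch4 (-0.75), Tmem11 (0.83), Tpgs1 (-0.57), Cat (-0.90, with 0.16 for its other probe set) and Srp9 (0.76). Across probe sets the rostral minus occipital difference of replicate 1 correlated with that of replicate 2 at r = -0.35. Of the probe sets that differed over 2-fold in both replicates, 73 had opposite and 11 the same direction, where dorsal against ventral had 1 and 272. All 8 tested genes of the caudal areal list differed in opposite directions, with medians of 1.26 in replicate 1 and -0.70 in replicate 2, and 7 of 10 genes of the rostral areal list did, with medians of -0.40 and 0.22.

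**Figure D3:**
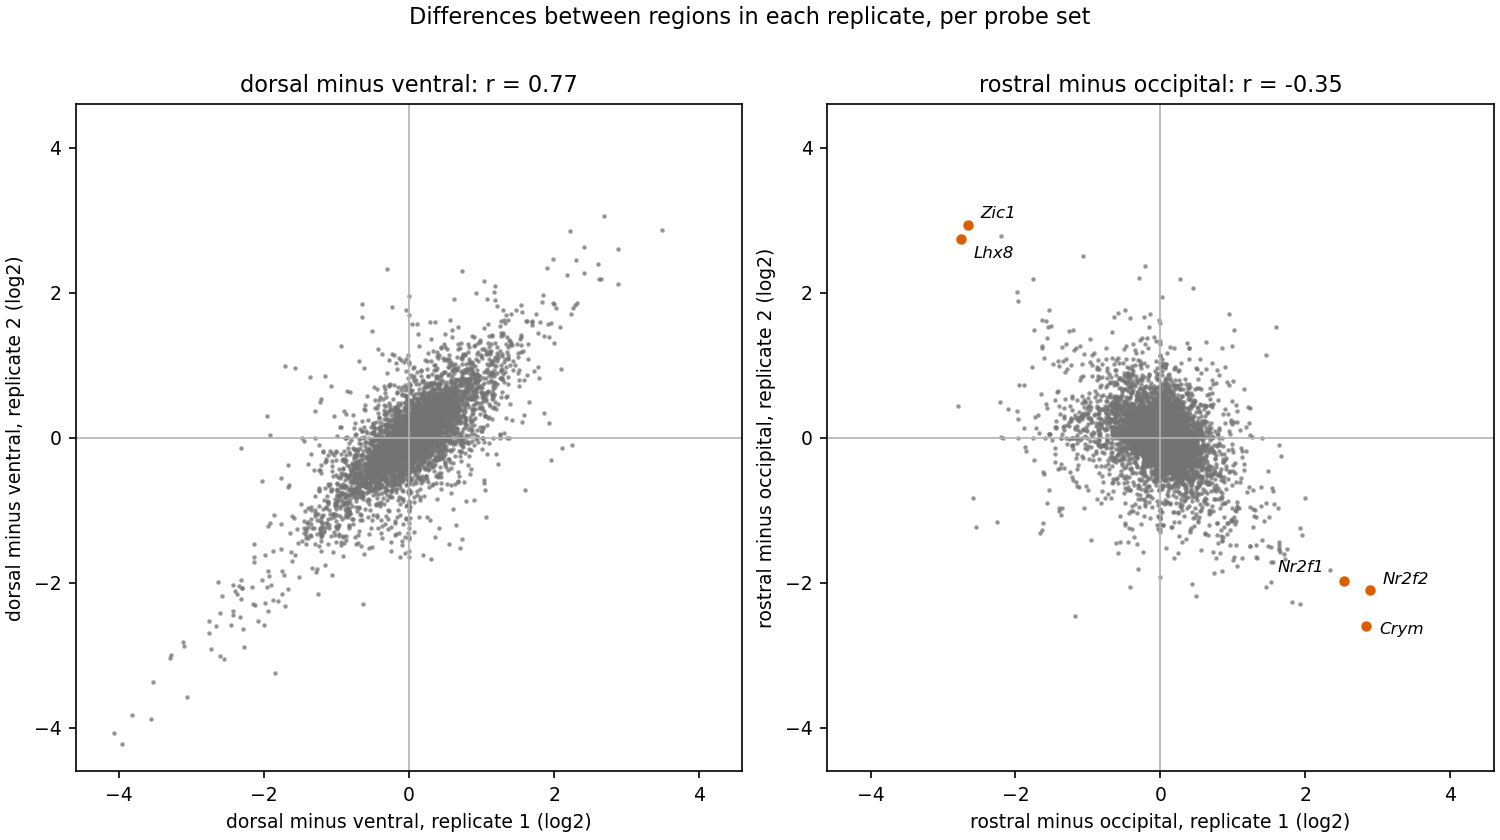
Log2 difference per probe set in replicate 1 (horizontal axis) and replicate 2 (vertical axis) for dorsal minus ventral (left) and rostral minus occipital (right); each point is 1 of 5832 probe sets. The left cloud rises (r = 0.77) and the right cloud falls (r = -0.35), and the 5 marked genes lie in the opposite quadrants.

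Rostral and occipital were each compared with the other 4 regions as well. Many probe sets reversed their rostral minus occipital difference between the replicates. The list calls here and in the next paragraph thus cannot be read as traits of either piece. In limma 0 probe sets passed for rostral (104 at an unadjusted p under 0.05) and 0 for occipital (126). Taking replicate number as a block, limma gave 209 and 303 at such a p, where 292 are expected by chance, and 0 passed in either. For rostral the 5 smallest p belonged to Npy (-0.75), the lipid phosphatase Plpp3 (0.74), the sphingosine-phosphate receptor S1pr1 (1.02), St6galnac5 (0.88) and Ripor2 (0.76), all with an adjusted p of 1. Npy measured 6506 ± 265 (SD, n = 2) against 13623 ± 9262 (SD, n = 8). For occipital they belonged to Tmem11 (-1.14 ± 0.16 SE, adjusted p = 0.325), Zfp61 (-0.71), Apoe (0.97), Ripor2 (0.79) and Mdk (0.75), none of which passed. No list member passed in either region over all probe sets. In the lists called for these regions 1 member passed in each region adjusted over the list alone, Npy in the GABAergic list, which was lower. Radial glia genes had medians of 0.31 in rostral (adjusted p = 3.51e-06) and 0.32 in occipital (adjusted p = 4.93e-05), each with an adjusted p = 0.242 with an estimated correlation, and with ventral out of the reference both calls were lost (0.151 and 0.262). The cell cycle list had medians of 0.21 (adjusted p = 3.27e-06, and adjusted p = 0.369 with an estimated correlation) and 0.15 (adjusted p = 0.000353, and adjusted p = 0.455 with an estimated correlation), and both turned downward with ventral out of the reference (adjusted p = 0.0797 and 0.0334). The GABAergic list had medians of 0.32 (adjusted p = 0.00542, and adjusted p = 0.421 with an estimated correlation) and 0.34 (adjusted p = 0.00147, and adjusted p = 0.369 with an estimated correlation). Without rostral replicate 2 the rostral calls of the cell cycle (0.523) and GABAergic (0.821) lists were lost. Without occipital replicate 1 the occipital GABAergic call was lost (0.989) and the occipital cell cycle list turned downward (0.559).

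In the rostral piece the rostral areal list had a median of -0.06 (adjusted p = 0.022, and adjusted p = 0.369 with an estimated correlation), and its call was lost without rostral replicate 1 (0.571), without occipital replicate 1 (0.359) or with ventral out of the reference (0.625). The subplate and Cajal-Retzius list had a median of 0.32 there (adjusted p = 0.022, and adjusted p = 0.285 with an estimated correlation), and its call was lost without rostral replicate 1 (0.561), ventral replicate 1 (0.0979) or medial replicate 1 (0.0530), with replicate number as a block (0.0734), without the filter (0.0879) and with means over probe sets (0.195).

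Each region was also set against the whole hemisphere, which holds all pieces together. In the ventral piece Mdk was 7.13-fold lower than in the hemisphere (2189 ± 452 against 15489 ± 1838, SD, n = 2 each; adjusted p = 0.00224) and Nfix 5.10-fold lower (adjusted p = 0.0287). Rasgrp2 was 3.77-fold higher there (adjusted p = 0.025), and so was Cyc1, a mitochondrial cytochrome (4.68-fold, adjusted p = 0.0315), whose other probe set differed by -0.17. In the medial piece Scg2 was at least 3.98-fold lower (adjusted p = 0.0104), Vsnl1 3.21-fold lower (1087 ± 71.5 against 3486 ± 61.9, SD, n = 2 each) and Pter at least 2.28-fold higher. In the dorsal piece Ccl4 was at least 4.67-fold higher (adjusted p = 0.0032), and St6galnac5 (4.39-fold) and Ripor2 (3.59-fold) were lower. limma passed 63 probe sets for ventral, 23 higher and 40 lower, 4 for medial and 3 for dorsal. It passed 0 for rostral (234 at an unadjusted p under 0.05) and 0 for occipital (146), so 70 in all. For rostral Npy (-1.07, adjusted p = 0.399) and for occipital Sf3a2 (2.96, adjusted p = 0.814) had the smallest p. Of the genes named here Mdk kept its call under every alternative run. With replicate number as a block St6galnac5 and Ripor2 lost theirs (adjusted p = 0.0647 each). At double the floor St6galnac5 (0.199), Ripor2 (0.139), Ccl4 (0.0769), Scg2 (0.0873), Vsnl1 (0.0671), Pter (0.66) and Cyc1 (0.0669) lost theirs. Nfix and Rasgrp2 lost theirs without the filter (0.115 and 0.0924), as did St6galnac5 (0.116), Ripor2 (0.105), Vsnl1 (0.076) and Cyc1 (0.115). On an arcsinh scale Pter (0.429), Vsnl1 (0.0603), St6galnac5 and Ripor2 (0.054 each), Cyc1 (0.0548) and Rasgrp2 (0.0569) lost theirs. At a lower floor Pter (0.153), Cyc1 (0.0587) and Rasgrp2 (0.0668) did. Pter did with a trend and robust variances (0.277), and Ripor2 (0.0566) and Nfix (0.0558) without the arrays labelled rostral or occipital. Mdk and Ccl4 alone kept theirs whichever array was left out. The total of 70 was 246 with the block, 6 and 4 without ventral replicate 1 and 2, 27 and 8 without hemisphere replicate 1 and 2, 30 without either medial and 20 without either dorsal replicate.

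The hemisphere was compared with the unweighted mean of the 5 regions to see whether the whole differs from its parts. limma passed 0 probe sets, and 277 had an unadjusted p under 0.05, where 292 are expected by chance. With replicate number as a block 537 had such a p, and without hemisphere replicate 1 or 2 it was 453 or 797, still with 0 passing. Cyc1 (-1.82), Saysd1 (-1.28) and the splicing factor Sf3a2 (-2.20), each with an adjusted p of 0.409, Tef (-1.02) and Ccrl2 (0.90) had the smallest p and did not pass. Without occipital replicate 2 the count was 1.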

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

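Chosen after the data were seen were the alternatives without the arrays labelled rostral or occipital and those with the ventral piece out of the reference mean; the others were planned. Where 1 of 2 replicates is left out, the lone array is assumed to vary like the other groups. Under the alternatives run, the 149 calls of named genes gave 3259 values: 2549 kept the call, 710 lost it and 0 reversed. The calls that were never lost numbered 29 of the 149. A reversal was unlikely from the start, since these genes had passed with the same sign in both replicates and the alternatives refit those arrays. Of 30 named genes that had not passed, 1 passed in 1 of 607 values. Of the 33 list calls, 535 of 619 values kept the call, 81 lost it and 3 reversed. These reversals are the cell cycle list in the rostral and occipital pieces with ventral out of the reference (adjusted p = 0.0797 and 0.0334), whose construction removes the piece with the lowest values, and in the occipital piece without occipital replicate 1 (0.559, where the other arrays left out gave values down to 1.84e-10 with no reversal), where the cause was not tested. Counts of probe sets also moved. With replicate number as a block, which also takes out what arrays of a number share, counts were 442 for the F-test, 256 for medial, 45 for dorsal, 938 for ventral, 587 for dorsal against ventral (313 higher and 274 lower in the dorsal piece, the reverse of 145 and 163, as with 0.5 times the floor, 152 and 145, and a stricter filter, 124 and 114) and 246 for regions against the hemisphere; deviations from the group mean correlated above 0.1 between groups in 14 of 15 pairs of groups, from -0.06 to 0.56, but the labels do not say that equal numbers share a dissection. Without a filter, which tests more probe sets, counts were 124 for the F-test, 3 for rostral, 4 for occipital, 188 for dorsal against ventral and 7 for the hemisphere against the mean of the regions. Without the arrays labelled rostral or occipital, which changes the regions compared, the reference and the estimate of the spread together, they were 383 for the F-test, 166 for medial and 28 for dorsal, and with ventral out of the reference 5 for medial and 8 for dorsal. Dorsal had 7 with 0.5 times the floor, 7 on an arcsinh scale and 7 when only the arrays compared were fitted; medial had 124 in the last of these, and the hemisphere against the mean of the regions had 1 at double the floor. The cause of these was not tested. After quantile normalization medial had 24 higher and 55 lower, so that 30.4% were higher against 40.5%. Camera with an estimated correlation called 0 of the lists in limma, against 33. Leaving out 1 array gave 11 to 234 for the F-test, 0 to 124 for medial, 2 to 16 for dorsal, 91 to 653 for ventral, 0 to 0 for rostral, occipital and rostral against occipital, 49 to 347 for dorsal against ventral, 4 to 66 for regions against the hemisphere, 0 to 1 for the hemisphere against the mean of the regions and 29 to 39 list calls. Signal over background limits what could be seen: 46.9% of the probe sets reached 2 times the floor on 2 arrays and were tested; the rest entered only the alternative without a filter.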

Other observations

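Chosen after the result was seen were the tests of exchanged labels, including the paired comparisons, striatal tissue, RNA integrity, the share of progenitors, GABAergic cells, microglia, the floor for Ccl4 alone and the ventral medians by number. The list tests, the limma calls of members, the test of an effect of the replicate number and the test of the floor on Nfe2l3 and Ccl4 were planned.

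Some gene groups moved in part in the ventral piece without a call of the whole list. Of 27 genes of axon guidance and adhesion, Epha7 (1.46), Efnb3 (0.92), Sema4a and the adhesion molecule Cdh13 (0.89) rose, and Nrp1 and the ephrin ligand Efnb1 (-1.26) fell. Among 7 subplate and Cajal-Retzius genes, the transcription factor Ebf2 (1.28) and the cyclin kinase inhibitor Cdkn1a (1.62) rose and Cxcr4 fell. Of 14 upper layer genes Plxnd1 (1.43) rose and Id2 (-0.83) fell, with a median of -0.51, and of 10 deep layer genes Cdh13 rose and Fezf2 and Nfib fell, with a median of -0.64. In the rostral areal list the retinoic acid-binding protein Crabp1 (2.09) and Epha7 rose and the phosphatase Dusp6 (-0.84) fell.

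Over the 5 regions, list medians ran from -0.14 to 0.22 for 15 genes of meninges and fibroblasts, where Igfbp2 (-0.48) fell in the ventral piece, from -0.18 to 0.09 for 5 genes of endothelial cells and pericytes, and from -0.10 to 0.09 for 6 erythroid genes, where the carbonic anhydrase Car2 (0.86) rose in the ventral piece. The 7 tested genes of microglia and macrophages had medians of -0.14 to 0.18. That list was called lower in the dorsal piece (adjusted p = 0.0296, and adjusted p = 0.455 with an estimated correlation), with Apoe as its passing member, and lost the call without replicate 2 of the dorsal (0.186), medial (0.0519), ventral (0.0655), rostral (0.0773) or occipital (0.0647) piece, after quantile normalization (0.0619), with replicate number as a block (0.0699), without the filter (0.287) and with means over probe sets (0.0988). The olfactory bulb list had medians of -0.27 to 0.23 and no call. In the ventral piece its median was 0.23 but its mean -0.15, and the meninges list had a median of 0.22 but a mean of -0.02. The choroid plexus (3 tested genes), diencephalon (2), retinoid (4), oligodendrocyte (3) and muscle (3) lists were too small to test. Choroid plexus medians ran from -0.60 in the ventral to 0.78 in the occipital piece, and diencephalon medians from -1.23 in the dorsal to 1.17 in the ventral piece. The sodium pump subunit Atp1b1 (1.04) of the former, Tcf7l2 of the latter and Crabp1 of the retinoid list passed with a rise in the ventral piece. The probe sets of Atp1b1 and Tcf7l2 are of the kind that can match several members of a sequence family. Medians ran from -0.22 to 0.14 for the retinoid, from -0.22 to 0.50 for the oligodendrocyte and from -0.06 to 0.24 for the muscle list.

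The arrays labelled rostral and occipital differed in opposite directions in the replicates. An effect of the replicate number carried unevenly by these arrays is argued against, since the reversed part of the difference correlated at 0.134 across probe sets with the mean difference between numbers in the other 4 groups. An exchange of the rostral and occipital labels of 1 number is a candidate explanation that stays open: it was drawn from the correlation of -0.354 between the replicates' rostral minus occipital differences, so that value does not test it, nor do the 38 probe sets that limma passed for the crossed pairs of these 4 arrays (0 by label, with 62 at an unadjusted p under 0.05, and 0 by number, with 244). With the mean of the other 4 groups of the same number taken out, the crossed pairs correlated at 0.33 (rostral 1 with occipital 2) and 0.14 (rostral 2 with occipital 1), the pairs of a label at -0.04 and -0.13, and the pairs of a number at 0.21 and -0.04, so that 1 of the crossed pairs lay below a pair that shares only its number. The pairs of a number had the same mean taken out, which by itself raises their correlation. The values 0.21 and 0.14 therefore cannot be weighed against each other. Before that mean was taken out, rostral 2 with occipital 1 had the highest correlation of these pairs, 0.963. The other crossed pair, rostral 1 with occipital 2, correlated at 0.944. The pairs of a label correlated at 0.934 and 0.936, and the pairs of a number at 0.949 and 0.949. So 1 crossed pair lay above all the others and 1 lay below the pairs of a number, which does not decide the exchange either. Were the labels of 1 number exchanged, the areal lists would point to number 1. There the caudal list was higher (median 1.26) and the rostral list lower (-0.40) in the piece labelled rostral. In number 2 these medians were -0.70 and 0.22, the order the labels would give. This reading takes the piece titled rostral as rostral, where the protocol text lists a lateral piece. The exchange itself was not tested this way. Whether pieces taken at different planes in each dissection would give the same values was not tested either.

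In the ventral piece 19 of 30 cell cycle genes fell, and of 15 GABAergic genes 6 rose and 1 fell. Neither list was called by camera with an estimated correlation (adjusted p = 0.242 each). These shifts have several possible explanations. RNA integrity stays open, as the beta-actin ratio lay below the range of the other regions in 1 of the 2 numbers, ventral replicate 1, and within it in the other. The ventral median of the cell cycle list was -1.18 in replicate 1 and -0.97 in replicate 2, and that of the GABAergic list 0.95 and 0.81, so both were smaller in size where the ratio was within the range. Hemisphere replicate 1, with a lower ratio of 0.604, had Gad1 at 12155, below the ventral mean of 20952. The hemisphere also holds pieces with less Gad1, so this level does not test RNA integrity. On hemisphere replicate 2, with a ratio of 0.804, Gad1 was 9462. The GAPDH ratio likewise lay below the range of the other regions on ventral replicate 1 (0.982 against 1.05 to 1.16). It lay within that range on ventral replicate 2 (1.09 against 1.00 to 1.14). Tissue of the striatum or its mantle in the ventral piece may contribute, since the striatal list had a median of 0.66, with 4 members rising and 0 falling by limma. A smaller share of dividing progenitors may contribute too, since the radial glia list had a median of -0.65, with 5 members falling and 0 rising by limma. These stay open too, as does a difference between cortical regions as such, which was not tested apart from them.

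Npy, Nfe2l3 and Ccl4 were higher in the dorsal piece. More GABAergic cells there are argued against for Npy, since the GABAergic list without it had a median of -0.70, with 14 of 14 members below 0. More microglia or macrophages stay open for Ccl4. Their list had a median of -0.14, but 7 of its 20 genes on the array were above the filter and tested. A small rise in such cells could have been missed. For Nfe2l3 the floor could make the call: on an arcsinh scale without a floor its difference went from 1.40 to 2.04, its residual SD from 0.19 to 0.42 and its adjusted p to 0.0535, the larger of those of Nfe2l3 and Ccl4, so the call ended because the spread among low values grew. The floor alone is argued against for Ccl4, whose adjusted p on that scale was 0.00514, with a highest value of 0.014 over the alternatives against the other 4 regions; against the hemisphere its call was lost at double the floor (0.0769). A regional difference in the expression of these genes stays open and was not tested.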
